A study of Mus musculus with 321 samples.

How the data were processed

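The series examined how the transcription factor Tcf-1, encoded by Tcf7, relates to open and repressed chromatin in the mouse. ATAC-seq, which maps open chromatin, was made from CD4 CD8 double-positive (DP) thymocytes of wild-type (WT) and Tcf-1 knockout (KO) animals, and from NIH3T3 fibroblasts carrying an empty retrovirus (Empty RV) or a retrovirus expressing Tcf-1 (Tcf-1 RV). ChIP-seq of the repressive histone marks H3K27me3 and H3K9me3 in NIH3T3 cells without Tcf-1, and of Tcf-1 itself in Tcf-1 RV cells, completed the files used. Of the 321 samples of the series, 16 had a file of their own: 12 ATAC-seq and 4 histone libraries. The RNA-seq, single-cell ATAC-seq, input, Empty RV Tcf-1 ChIP-seq and Tcf-1 RV histone libraries were not analysed here.

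Per the submitters' processing notes, the tools FastQC, Trim Galore, Bowtie2 2.2.9, STAR 2.5, Picard and MACS2 were used, and the builds GRCh37, GRCm38 and mm10 were listed. Which tool served which file is not given in the sources used here. mm10 and GRCm38 are names of the same build, and all coordinates below are GRCm38. Each ATAC-seq file that the authors deposited holds genomic start and end positions of peaks and no height, score or p-value. The deposited Tcf-1 file is 1 pooled list of 40562 single-base summits with a score per summit whose scale is not stated (0.0579 to 259.0). The deposited histone files hold SICER islands per library, with the read count of the ChIP and of the control library, the ratio (fold) of ChIP over control scaled by 1 constant per file, and a p-value and adjusted p-value per island. Every adjusted p-value in them was below 0.01. No read depth is stated for the ATAC-seq libraries, so the length of each peak list was the only measure of how much was called.

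Peaks on unplaced sequences, 293 in all, were left out. The gene table came with assembly GRCm38.p6 and gave each gene's start and end but no strand, exons or sequence. Peaks within 1 kb of either end of a protein-coding gene were therefore counted as gene-end peaks in place of peaks near a transcription start site, and all others as distal. A region was assigned to the nearest of 21890 genes (21887 protein-coding genes and 3 listed T cell receptor segments) within 50 kb, at distance 0 if it lay inside the gene. Motif searches, planned before the data were examined like the other tests and alternatives, could not be run without sequence. As a check of the build, 18.1% to 66.9% of the peaks of a library were gene-end peaks, against 3.67% to 4.36% after the peaks had been shifted along the chromosomes.

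For each comparison the peaks of all libraries were merged where they shared at least 1 bp. A library held a region if it had a peak there. DP regions were called lost if both WT libraries and neither KO library held them, gained if the reverse was true, and kept if all 4 libraries held them. NIH3T3 regions were called gained if all 4 Tcf-1 RV libraries and no Empty RV library held them, and lost in the reverse case. No other pattern of 4 against 4 libraries has a two-sided Fisher exact p under 0.05. A region held a Tcf-1 summit if a summit lay within it, and lay in H3K27me3 or H3K9me3 if its midpoint was in an island called in both replicates. It was open in DP thymocytes if it overlapped a peak called in both WT libraries. A comparison class of 5640 regions was formed from those called in 4 of the 8 NIH3T3 libraries in any combination other than the arms.

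Values per library were compared with exact two-sided permutation tests, whose smallest p is 0.0286 for 4 against 4 libraries and 0.333 for 2 against 2. Shares of regions were compared with two-sided Fisher's exact tests over regions, and 95% Wilson intervals were given for shares. Intervals cover counting error only, and neighbouring regions are not independent. P-values were adjusted by Benjamini-Hochberg within each family of tests. Nothing in the labels says that replicates came from separate animals or cultures, so each p measures only the spread between these libraries. Replicates carry the same numbers in both arms. After removal of the arm means, NIH3T3 libraries of the same number were correlated (0.125 to 0.260 over regions in the 4 pairs), so their numbers were treated as pairs. Tags in the names of the deposited files put NIH3T3 replicates 1 and 2 of both arms on day 2 and replicates 3 and 4 on day 4. The pooled list of Tcf-1 summits carries a day 2 tag. The labels give no day, and the tags were used only as batches. Between arms, libraries of different number but the same tag were also correlated (0.0648 to 0.194), and all values across tags were negative. The pairs may therefore reflect the tag as much as the number.

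Fixed lists held 255 genes in 15 groups: the T cell receptor complex and its signalling, DP thymocyte genes, T lineage transcription factors, cytokine and homing receptors, Wnt pathway targets, NK, innate lymphoid and effector genes, B cell markers, myeloid and dendritic markers, erythroid and megakaryocyte markers, thymic epithelium markers, fibroblast and mesenchymal genes, AP-1 and serum response genes, developmental homeobox and Polycomb genes, apoptosis and survival genes, and housekeeping genes. All 255 symbols matched the gene table. The number of list genes with a differing region was compared, two-sided, with 10000 random lists matched on the number of merged regions per gene. Genes to name were those with the most differing regions in each list (up to 3) and in the genome (4 per direction), plus Tcf7. Summit positions were compared with 100 circular shifts along each chromosome.

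Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The region calls were tested on simulated data with the real list lengths and 200 planted regions. For the NIH3T3 comparison (77882 regions), all 200 were recovered when every Tcf-1 RV library held them and 63.5% when each held them at a rate of 90%, where 65.6% is the share that 4 independent draws allow. For the DP comparison (31628 regions) the shares were 100% and 81.5%. Further regions were called without being planted: in 20 runs without planted regions, 27.8% to 28.7% of the DP regions were called lost (31.7% in the data) and up to 0.212% of the NIH3T3 regions gained (1.08% in the data). The simulated rates and list lengths came from the real libraries of both arms, so these runs cannot say how much of the real loss is due to list length. The list test called 1.0% of 600 lists without a planted effect in NIH3T3 and 1.5% of 600 in DP at p under 0.05. A list in which every gene was given 1 further differing region was called in 40 of 40 runs for NIH3T3 and in 2 of 40 for DP, where lost regions are common and the test has little power. Alternatives covered the overlap that counts as called, slack around absent regions, the sex chromosomes, the number of libraries, pairing, the day tags, the island and summit sets, gene assignment and leaving out each library. Those that needed a peak score could not be run. A limit to the widest peaks, equal in number in every library, replaced them. It, the class of regions called in 4 of 8 libraries and a summit window of 100 bp on each side of midpoints were chosen after the data had been seen.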

Results

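Open chromatin was mapped by ATAC-seq in 2 WT and 2 Tcf-1 KO libraries of DP thymocytes, the stage at which developing T cells carry both CD4 and CD8. It was also mapped in 4 Empty RV and 4 Tcf-1 RV libraries of NIH3T3, an established mouse embryonic fibroblast line that is not of the T lineage. The DP peak lists held 23249 and 30985 peaks in WT and 11171 and 12209 in KO. The NIH3T3 lists held 22778, 34601, 46819 and 58026 peaks for Empty RV replicates 1 to 4 and 47623, 43527, 36583 and 62639 for Tcf-1 RV. H3K27me3 and H3K9me3 islands came from 2 libraries each of NIH3T3 without Tcf-1, and Tcf-1 binding from the 40562 pooled summits of Tcf-1 RV cells.

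The DP comparison asks which open regions of thymocytes depend on Tcf-1. Cd247, which encodes a receptor signalling chain, lost 8 of its 14 regions, among them chromosome 1: 165780451-165781172 at 860 bp from a gene end, and Trat1 lost 5 of 8. Among transcription factors, Runx1 lost 9 of 16 regions and Tox 8 of 10. At Cd8a, which encodes a coreceptor of the DP stage, 3 of 4 regions were lost, including chromosome 6: 71373348-71373640 just inside the gene, and at Cd69 4 of 8 were lost. Across the genome 10032 regions were lost and 45 gained. The lost regions were 45.7% (95% CI 45.0 to 46.4) of the 21952 regions called in both WT libraries.

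Loss fell mainly on regions away from gene ends, where enhancers commonly lie. Of the distal regions called in both WT libraries, 8620 of 13240 (65.1%, 64.3 to 65.9) were lost, against 1412 of 8712 gene-end regions (16.2%, 15.4 to 17), an odds ratio of 9.64 (9.02 to 10.3). Within strata of region width the odds ratio was 4.60 (4.25 to 4.99), and between libraries of 1 group it was 0.660 to 2.77. Per library, distal peaks numbered 17197.5 ± 4588.4 in WT and 4111.5 ± 584.8 in KO, a ratio of 4.18, and gene-end peaks 9919.5 ± 881.8 and 7578.5 ± 149.2, a ratio of 1.31 (SD, n = 2 per arm, exact permutation p 0.333 for each, the smallest this design allows). The genes with the most lost regions were large ones: Wwox lost 14 of 30, Pde4d 14 of 30, Nfia 13 of 26 and Sgms1 12 of 19. At Tcf7 itself, the region at chromosome 11: 52268627-52268890 inside the gene was called in both WT and neither KO library, while 52275323-52275860 was called in all 4. The labels do not say which part of Tcf7 the knockout removes. Gained regions were scattered. Acnat1, Tmem267, Ctnnd2 and Gm39469 had 2 each, and 15 of the 45 (33.3%, 21.4 to 47.9) lay in fibroblast H3K9me3 islands, against 2.92% of the kept regions.

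**Figure D1:**
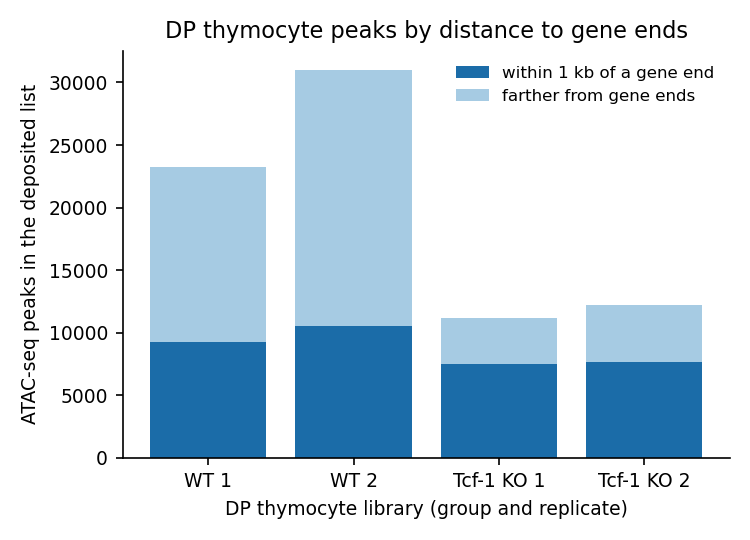
Number of ATAC-seq peaks in each DP thymocyte library, with peaks within 1 kb of a gene end in dark blue and peaks farther away in light blue. The WT libraries held 9296 and 10543 gene-end peaks and the KO libraries 7473 and 7684, while the distal part was several times shorter in both KO libraries.

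No fixed gene list lost regions in more or fewer genes than matched random lists after adjustment. The test has little power in DP, where a planted list was called in 2 of 40 runs, so a preference for any list is not excluded. Among genes with at least 1 region, loss touched 12 of 20 of the T cell receptor list (Cd247, Trat1; 13.8 in random lists), 13 of 19 DP genes (Cd69, Cd8a), 16 of 21 T lineage transcription factors (Runx1, Tox; 16.5) and 13 of 16 cytokine and homing receptors (Il2ra 4 of 7 regions, Cxcr4 4 of 7). It touched 9 of 11 Wnt targets (Cd44 4 of 7, Myc 3 of 4), 5 of 7 NK and effector genes (Klrb1c 3 of 5), 3 of 8 myeloid genes, 2 of 4 erythroid genes and 3 of 5 thymic epithelium genes (Epcam 2 of 4). It also touched 4 of 14 fibroblast genes (Fbn1 2 of 2), 7 of 14 AP-1 genes (Jun 2 of 4), 3 of 6 homeobox genes and 9 of 13 apoptosis genes (Bcl2l1 3 of 9). B cell markers came closest to an excess, with 7 of 8 genes (Ebf1 4 of 5 regions) against 3.52 in random lists. Their two-sided p against random lists was 0.0156, adjusted 0.423 over the 15 lists and both directions in DP. Housekeeping genes came closest to a deficit, with 2 of 15 (Actb 2 of 4 regions) against 5.73 (p 0.0282, adjusted 0.423). No list gene had a gained DP region. The KO lists were 2.32 times shorter, and the files do not say whether fewer open regions or fewer calls made them so. With the same number of the widest peaks in every library, a limit that by itself draws lost and gained regions towards equal numbers, 1360 regions were lost and 956 gained, and 88.3% of the latter were in the full lists of both WT libraries. Of the genes named here, Nfia then had 5 lost regions, Pde4d 3, Ebf1 and Sgms1 2 each, and Cd247, Tox, Cd69, Cd44, Myc, Epcam and Jun 1 each, while Runx1, Cd8a, Trat1, Tcf7, Wwox, Il2ra, Cxcr4, Klrb1c, Bcl2l1, Fbn1 and Actb had none.

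The NIH3T3 comparison asks whether Tcf-1 opens chromatin when expressed ectopically in a fibroblast. The gene with the most gained regions was Tcf7, with 4 of 15, all with a Tcf-1 summit and all inside the gene: chromosome 11: 52256743-52257251, 52257684-52257941, 52261512-52261763 and 52281977-52282373. The last of these lay in an H3K27me3 island. Reads from the Tcf-1 sequence carried by the retrovirus would map to exons of Tcf7, so peaks and summits there cannot be assigned to the cellular gene from these files. Zfand3, Tasp1 and Tanc1 gained 3 regions each. Among T lineage factors Notch1 gained 1 of 7 regions (chromosome 2: 26500077-26500364) and Hes1 1 of 12 (chromosome 16: 30059455-30059744), both without a summit. Krt5, Hoxb1, Pdgfrb, Col3a1 and Postn gained 1 each with a summit, while Col1a2 and Twist2 lost 1 each without one and Adgrl3 lost 2. With the same number of the widest peaks in every library, only Tcf7 and Zfand3 of these genes had a gained region (1 each) and none had a lost one. When a peak had to cover at least 50% of a region, Tasp1, Pdgfrb and Col3a1 had no gained region. With regions assigned only within 10 kb of a gene, Hoxb1, Col3a1 and Postn had no gained and Twist2 no lost region, and in DP Cxcr4 and Epcam had no lost and Gm39469 no gained region. When a region counted as absent only without a peak within 1 kb, Gm39469 had no gained region and Tmem267 1, and Actb and Jun had 1 lost region each.

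**Figure D2:**
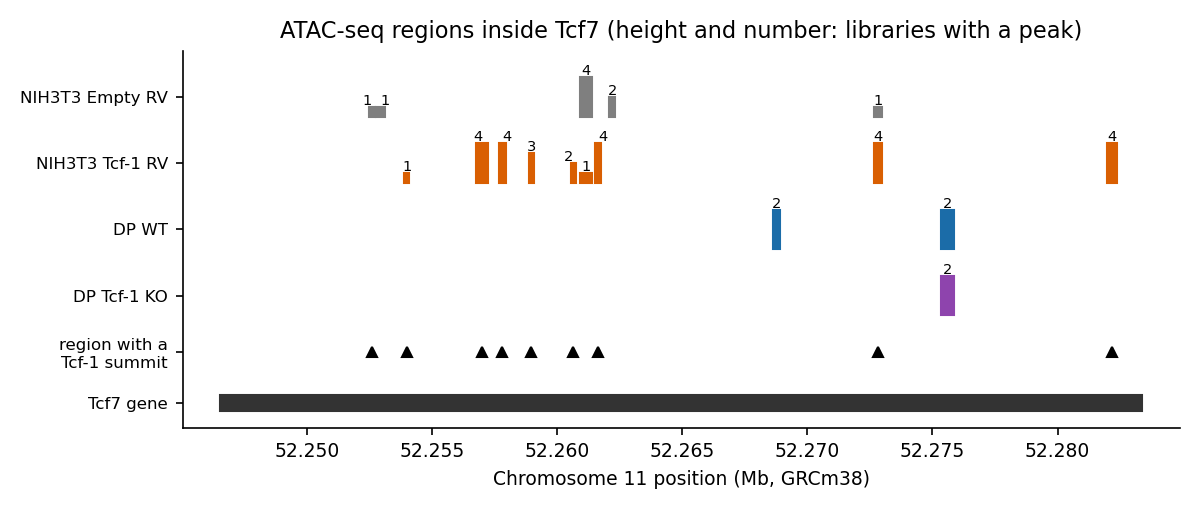
Open regions inside Tcf7 on chromosome 11 (GRCm38, position in Mb). Bar height and the number above it give how many libraries of the group had a peak (of 4 for NIH3T3 and of 2 for DP), and triangles mark NIH3T3 regions with a Tcf-1 summit. The 4 gained regions were present in all Tcf-1 RV and no Empty RV libraries.

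In all, 839 of 77882 NIH3T3 regions were gained and 86 lost. A Tcf-1 summit lay in 680 of the gained regions (81.05%, 78.3 to 83.6), in 1 lost region (1.16%, 0.206 to 6.30), in 38.8% of the 18682 regions called in all 8 libraries and in 18.5% of those called in 4 of 8 in another combination (odds ratio 18.8, 15.6 to 22.6, for gained against these). Gained regions were distal, with 21 (2.503%) at gene ends against 34.8% of those called in all 8 and 7.55% of those called in 4 of 8 (odds ratio 0.321, 0.207 to 0.498), and 439 lay inside genes. Called by pairs of the same replicate number, with 1 of the 4 pairs allowed to show no difference, 3523 regions were gained and 646 lost. With all 4 pairs required this rule equals the main one, so the higher counts come from the looser rule and not from pairing. The counts differed between the day tags: 9636 regions were gained and 391 lost on day 2, but 1503 gained and 2467 lost on day 4. On day 2 the Empty RV lists were shorter on average than the Tcf-1 RV lists (28689.5 and 45575 peaks). On day 4 they were longer (52422.5 and 49611 peaks), so under both tags more calls went to the arm with the longer lists. The summit share of gained regions was 54.02% on day 2 and 62.01% on day 4, and that of lost regions 2.56% and 4.62%. All summits came from the list tagged day 2, so both values rest on binding under that tag.

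**Figure D3:**
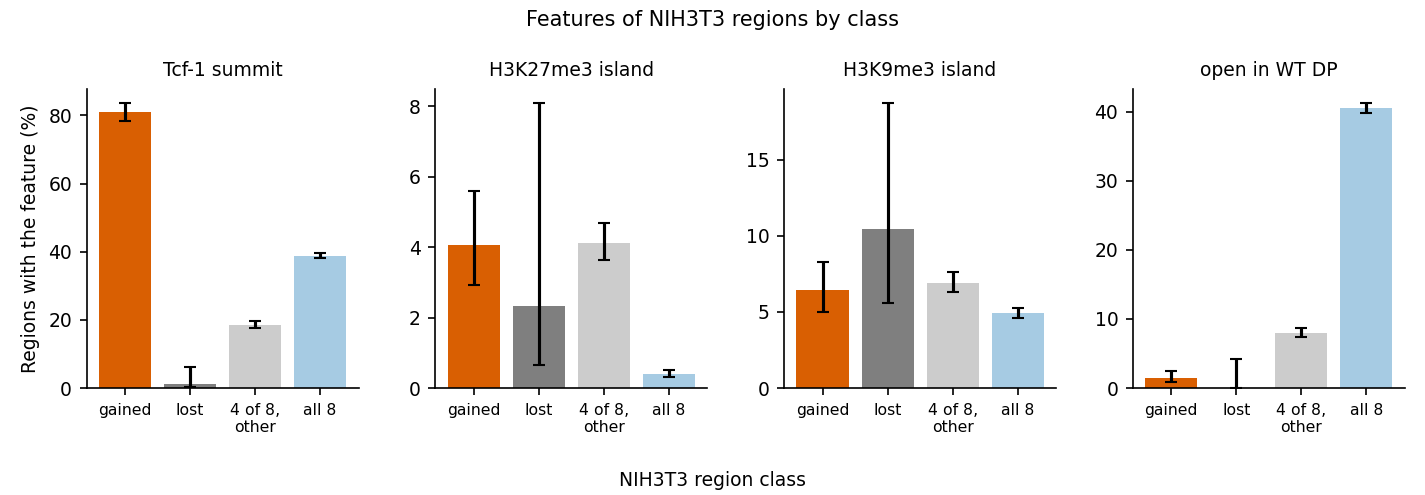
Percentage of NIH3T3 regions with a Tcf-1 summit, in an H3K27me3 or H3K9me3 island, or open in both WT DP libraries, by class (95% Wilson intervals). Classes are gained (839 regions), lost (86), called in 4 of 8 libraries in another combination (5640) and called in all 8 (18682). Gained regions held summits most often, at 81.05%.

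Each Tcf-1 RV library had more of its peaks at Tcf-1 summits than its Empty RV partner, although the test between arms did not pass. Peaks with a summit made up 26.1% ± 2.95 of Empty RV peaks and 33.3% ± 4.09 of Tcf-1 RV peaks (SD, n = 4 per arm), a difference of 7.16 points with an exact two-sided permutation p of 0.0571 (adjusted 0.229 over 8 tests). The Tcf-1 RV library was higher in 4 of 4 pairs, by 5.12 to 9.04 points (exact sign-flip p 0.125, the smallest 4 pairs allow), and the difference was 8.08 points on day 2 and 6.24 on day 4. Tcf-1 RV peaks were also wider in 4 of 4 pairs (median 310.5 ± 13.67 bp in Empty RV and 327.8 ± 7.14 bp in Tcf-1 RV, exact p 0.0571, adjusted 0.229), and a wider peak has more room for a summit. The pairs differed by 1 to 45 bp, and Empty RV replicate 1 (290 bp) stood apart from the other Empty RV libraries (317 to 318 bp). With summits counted only within 100 bp of the peak midpoint, an alternative chosen after the widths were seen, the difference was 6.86 points (exact p 0.0571). The number of peaks (40556 ± 15230.9 against 47593 ± 11017.2, exact p 0.457), the H3K27me3 share (1.59% ± 1.01 against 2.24% ± 0.804, exact p 0.343) and the H3K9me3 share (5.54% ± 0.200 against 5.50% ± 0.257, exact p 0.857) differed by less than the spread between replicates. So did the DP-open share (27.8% ± 6.40 against 24.5% ± 4.22, exact p 0.371) and the gene-end share (24.9% ± 5.29 against 22.5% ± 3.52, exact p 0.429). Day 4 libraries turned the direction of the peak number, DP-open and gene-end differences (-2811.5 peaks, 1.72 points and 1.65 points).

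**Figure D4:**
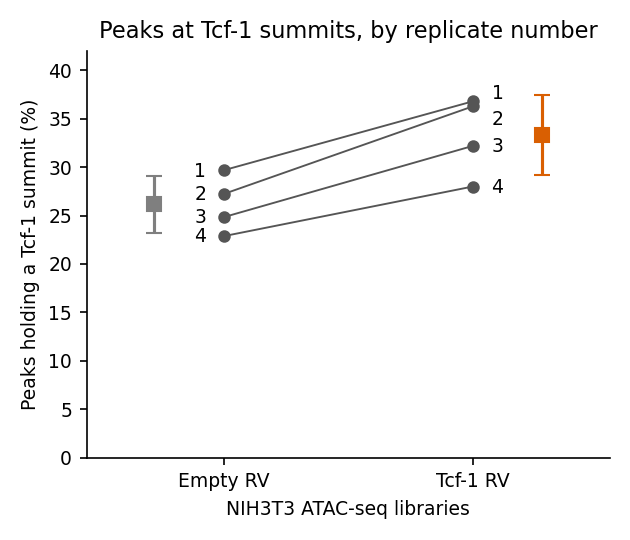
Percentage of the peaks of each NIH3T3 library that held a Tcf-1 summit. Lines join Empty RV and Tcf-1 RV libraries with the same replicate number (1 to 4), and squares with bars give mean and SD. Tcf-1 RV was higher in each of the 4 pairs.

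Whether Tcf-1 opened thymocyte sites or repressed sites was asked of the gained regions. Only 12 gained regions (1.43%, 0.820 to 2.48) were open in DP thymocytes, against 40.6% of regions called in all 8 libraries and 8.01% of those called in 4 of 8. Of these 12, 11 were lost in the DP KO, among them regions in or near Zbp1, Itpr2, Phldb2, Prim2 and Abi2, names chosen after the values were seen. The share lost was 71.8% in the 4-of-8 class (Fisher's exact p 0.192). Gained regions also lay at gene ends less often (2.503%, against 34.8% in all 8 and 7.55% in 4 of 8). The DP-open shares were not compared among distal regions alone. H3K27me3 islands held 34 gained regions (4.05%, 2.91 to 5.61), including 1 inside Tcf7, where retroviral reads are not excluded, and 1 within 50 kb of Hoxb1. That was above the 0.401% of regions called in all 8 but like the 4.13% of the 4-of-8 class (odds ratio 0.992, 0.689 to 1.43). H3K9me3 islands held 54 (6.44%), against 4.92% in all 8 (Fisher's exact p 0.0518, adjusted 0.0761) and 6.91% in 4 of 8. In 14 of 20 alternatives the unadjusted p against all 8 was under 0.05, among them the calls by replicate pairs (7.295%, Fisher's exact p 3.54e-08) and both day tags (6.63% and 6.85%), so the main value lay at the edge of the test. Of the gene lists, T lineage transcription factors had a gained region at 3 of 19 genes (1.74 in random lists), fibroblast genes at 3 of 24 (1.91), thymic epithelium at 1 of 9 and homeobox genes at 1 of 23. The T lineage genes were Notch1, Hes1 and Tcf7, and retroviral reads are not excluded at Tcf7. The other 11 lists had none, and no list passed. Loss touched 2 of 24 fibroblast genes (0.180 in random lists, p 0.0272, adjusted 0.816) and no gene of the other lists.

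In these fibroblasts H3K27me3 lay over many developmental and T cell genes. Its islands, which mark Polycomb repression, covered an end of 18 of 28 homeobox and developmental genes (Hoxb1, Hoxa9, Pax6), 11 of 20 T cell receptor genes (Cd3e, Zap70, Lck) and 11 of 20 DP genes (Rag1, Cd4, Cd8a), against 16.5% of all protein-coding genes (adjusted p 0.003, 0.003 and 0.006 over lists and both marks). B cell markers (8 of 14, Pax5 among them, adjusted p 0.0108), myeloid genes (8 of 15, Mpo and Csf3r, 0.0108) and T lineage factors (9 of 21, Gata3 and Bcl11b, 0.047) were also covered more often, and 0 of 24 fibroblast genes were (adjusted p 0.084). Examples were chosen after their values were seen. Some covered genes were close neighbours, such as Cd3e with Cd3d and Cd3g, Rag1 with Rag2, and several Hox genes. Neighbours can share an island but were counted as separate genes. The p-values of the lists may therefore be too small. No list passed for H3K9me3, where homeobox genes had 6 of 28 (adjusted p 0.28). H3K27me3 islands covered 288 and 276.2 Mb in the replicates, with 220.5 Mb in both, and H3K9me3 islands 412.4 and 447.1 Mb, with 347.8 Mb in both. The marks shared 9.94 Mb.

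Tcf-1 summits lay outside both marks more often than shifted positions did. H3K27me3 islands held 4.67% of the summits, against 9.52% ± 0.311 over 100 shifts, and H3K9me3 islands 6.67% against 14.7% ± 0.618. Regions open in any Empty RV library held 38.1% of the summits and regions open in both DP WT libraries 6.70%, against 0.462% after shifts. A further 25128 summits had no Empty RV peak, and 684 of these (2.72%) had a peak in all 4 Tcf-1 RV libraries. At summits in H3K27me3 islands alone the share was 27 of 1698 (1.59%, 1.1 to 2.30), lower than the 2.84% outside both marks (odds ratio 0.562, 0.382 to 0.826, Fisher's exact p 0.00152). In H3K9me3 islands alone it was 2.34% (odds ratio 0.828, 0.598 to 1.15). With the share open in at least 1 Tcf-1 RV library the odds ratios were 0.724 (0.640 to 0.819) and 0.941 (0.838 to 1.06). The gained Tcf7 region at 52281977-52282373 combined a summit with an H3K27me3 island. Reads from the retrovirus are not excluded there, neither for its peak nor for its summit.

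**Figure D5:**
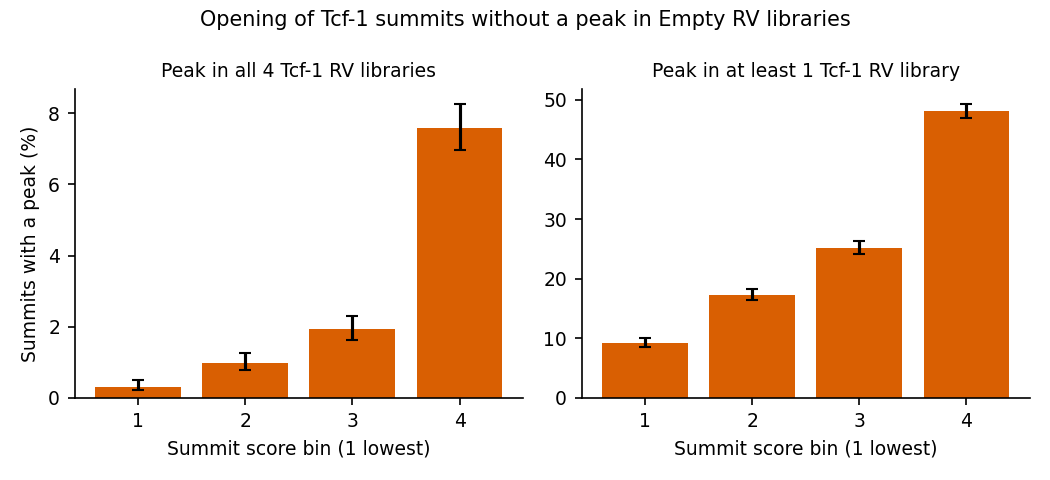
Percentage of Tcf-1 summits without an Empty RV peak that had a peak in all 4 (left) or in at least 1 (right) Tcf-1 RV library, in 4 bins of summit score with about equal numbers (95% Wilson intervals). The share in all 4 was 0.319% in the lowest bin and 7.59% in the highest.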

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

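Tests chosen after the result was seen were that for cells of another type in the KO sort, the counts of other splits of the NIH3T3 libraries, and the number of lost against gained DP regions with equal lists. The limit to the widest peaks, used in 2 of the tests, was also chosen after the data had been seen, and the other tests were set beforehand. Among 16 groups of measures, 1 library stood apart from its group: the median peak width of Empty RV replicate 1 was 290 bp, against 317, 317 and 318 bp in the other Empty RV libraries. It also had the shortest list (22778 peaks). Chance singles out about 1 in 20 such groups, and no explanation was tested. Without it, 377 NIH3T3 regions were lost in place of 86. Leaving out any library makes the rule ask less, so a higher count was set by the rule.

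Fewer calls and fewer open regions in the DP KO cannot be told apart by the number of lost regions, because no read depth is given. With the same number of the widest peaks in every library, lost regions were 1.42 times the gained ones (1360 and 956), but equal lists draw this ratio towards 1, and 844 of the 956 gained ones overlapped regions of the full lists of both WT libraries. The skew towards distal regions such as those at Runx1 and Tox was larger than between libraries of 1 group. Within strata of merged region width, the odds ratio of loss was 4.60 (4.25 to 4.99). Within groups it was at most 2.77, found for KO replicate 2 against 1. WT replicate 2 against 1 gave 0.660 (0.606 to 0.719), the other direction. Both pairs of lists were closer in length (12209 and 11171 peaks in KO, 30985 and 23249 in WT) than the WT and KO lists. These pairs therefore cannot show what the gap between WT and KO lists would give by itself in DP. Merged regions can also be wider where more libraries hold them, so the strata may partly follow the loss itself. Cells of another type would bring regions of their own, yet only 0.478% (upper bound 0.639%) of the regions of both KO libraries were absent from WT. Cells that share their open regions with WT DP thymocytes, or whose regions went uncalled in the shorter KO lists, are not excluded by this. Fewer calls or a weaker signal in the KO libraries and an effect of Tcf-1 on distal regions remain open.

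The gained NIH3T3 regions cannot be set apart from other structure in the libraries by their number alone. Of the 35 splits of the 8 libraries, 2 gave at least the 925 calls of the real split, so chance cannot be excluded, and the highest other value, 1987, came from the split by day tag. Among the 8 splits that part all 4 pairs, the next highest reached 12.9% of the real count. Counting only calls with a Tcf-1 summit, the real split was the highest of the 35 with 681, and the next had 323 (59 among the 8). Gained regions did not exceed lost ones within each tag: the lower count of gained regions was 1503, on day 4, against 2467 lost. With the same number of the widest peaks in every library, gained regions were still 2.66 times the lost ones (2.2 to 3.24), and 86.96% of them held a summit. This limit cannot decide whether longer lists in Tcf-1 RV were the source. Tcf-1 RV peaks were wider in all 4 pairs, and whether these gained regions were in the full Empty RV lists was not checked.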

How the results depend on the processing

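The limit to the widest peaks, the setting with DP gene-end regions alone and the summit window around midpoints were chosen after seeing the data. Alternatives based on a peak score and all motif tests were not run. Counts here are in units of 1000 regions. By replicate block, where 1 of the 4 pairs could show no difference, NIH3T3 gained 3.52 and lost 0.646. That rule asks less than the main one. In DP, where libraries of the same number were not positively correlated (-0.0505), the block has no basis, and it gave 21.6 lost and 0.423 gained because 1 of 2 pairs was enough. With at least 3 of 4 libraries, 2.85 were gained and 0.450 lost, since the rule asks less. Day 2 gave 9.64 gained, 0.391 lost and an H3K9me3 share difference of 0.160 points. Day 4 gave 1.503 gained, 2.47 lost, and turned the differences in DP-open share (1.72), gene-end share (1.65), peak number (-2811.5) and covered length (-0.890 Mb), with loss at 3 fibroblast genes, fewer than in random lists. The widest peaks gave 0.391 gained, 0.147 lost, a summit share difference of 10.3 points (exact p 0.0286), 0 fibroblast genes with loss, and in DP 1.36 lost, 0.956 gained and a gene-end share difference of 7.96 points, a fall that the limit itself favours, since kept DP regions (69.1% at gene ends) had a median width of 658 bp and lost ones of 335 bp. H3K9me3 islands of either replicate gave 0.0449 points. Among DP gene-end regions alone, 1.41 were lost. With summits within 100 bp of the midpoint, 71.3% of gained and 0% of lost NIH3T3 regions held one. Except for rules that ask less or limit the regions, the cause was not tested.

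Leaving out 1 library gave 0.849 to 2.64 gained and 0.087 to 0.377 lost NIH3T3 regions, H3K9me3 differences of -0.116 to 0.0812 points, summit share differences of 5.999 to 8.93 points, 10.9 to 18.4 lost and 0.049 to 0.204 gained DP regions, and 0 to 2 gene lists passing. Counts moved by over 1.5 times without Empty RV 1 (0.377 lost), Empty RV 4 (1.37 gained), Tcf-1 RV 1 (0.147 lost), Tcf-1 RV 3 (2.64 gained), Tcf-1 RV 4 (0.204 lost, and a summit share difference of 8.93 with exact p 0.0286), WT 1 (18.4 lost), WT 2 (0.185 gained), KO 1 (0.204 gained) and KO 2 (0.149 gained). Without WT 2, fibroblast (7 of 8) and housekeeping genes (2 of 15) passed (adjusted p 0.045 each), and without KO 1, B cell markers did (8 of 8, 0.042). A call asks less with 1 library fewer, so the counts of gained and lost regions could hardly fall when a library was left out. Over 20 settings the summit share was 54.02% to 86.96% in gained and 0% to 11.6% in lost NIH3T3 regions. Of the alternatives set beforehand for values that answer a comparison, 85.2% kept direction and call, 21 moved, 1 passed and 8 turned direction.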

Other observations

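The tests below were set before their results were seen, except the odds ratios within score bins, within strata of region width and with summits within 100 bp of midpoints. The class of regions called in 4 of 8 libraries was added after the data had been seen. Summits without an Empty RV peak opened more often the higher their score: a peak in all 4 Tcf-1 RV libraries was found at 0.319% (0.206 to 0.492) of the summits in the lowest of 4 score bins and at 7.59% (6.97 to 8.27) in the highest. The scale of the score is not stated. Within score bins, summits in H3K27me3 islands alone opened less often than those outside both marks (odds ratio 0.620, 0.418 to 0.918), and summits in H3K9me3 islands alone did so by less than counting error (0.805, 0.578 to 1.12). Peaks of a few libraries and a score of unknown scale do not exclude weaker binding in the islands.

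The H3K27me3 share of gained NIH3T3 regions, 4.05%, lay within the interval of regions called in 4 of the 8 libraries in another combination (3.64 to 4.68). The share fell with the number of libraries that held a region, from 6.67% for 1 library to 0.401% for all 8. The excess over constant regions therefore does not set gained regions apart from others called in as few libraries. A preference for H3K27me3 is not excluded. The odds ratio against the 4-of-8 class was 0.992 (0.689 to 1.43), and 1987 of the 5640 regions of that class followed the day tags.

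Regions lost in the DP KO were not marked by fibroblast Tcf-1 binding. Among distal DP regions, 5.90% of 8620 lost ones held a fibroblast summit, against 13.2% of 2851 kept ones (odds ratio 0.413, 0.359 to 0.475). A part of this came from width: within strata of region width the odds ratio was 0.650 (0.545 to 0.776), and with summits counted only within 100 bp of the midpoint 0.601 (0.484 to 0.746). Lost regions therefore held fibroblast summits less often than kept ones, which does not exclude that Tcf-1 binds them in thymocytes. Tcf-1 binding in thymocytes was not analysed here.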
